A study of Rattus norvegicus with 30 samples.

How the data were processed

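The tissue was the intermediate gray matter of the cervical spinal cord of rats after thoracic spinal cord injury or sham surgery, with 30 libraries of 1 rat each in 6 groups of 5. Per the labels' protocols, RNA was extracted on columns with DNase treatment, depleted of ribosomal RNA and made into strand-specific libraries that mark the second strand with dUTP. The design text states that the 5 rats per group were chosen on RNA quality and quantity from larger groups, so the rats are biological replicates that had passed that choice.

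The deposited values are raw counts per gene, 1 table per library, with whole numbers that differ in total between libraries. Per the submitters' processing notes, the authors used bcl2fastq 2.19.05, Trimmomatic, STAR 2.5.3a, featureCounts and Subread, with the genome build Rnor_6.0. The notes name no role or order for these tools. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap on opposite strands, and genes with near-identical copies, are therefore uncertain. Every table lists the same 32545 identifiers and holds no row without a gene, and 9816 of them had no count in any library.

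Groups and replicate numbers were taken from the sample titles. The library titled as the first sham rat of 1 week carries an injury in its surgery and source fields. It was kept as sham, and the counts were repeated without it and with it counted as injured. Within each group every pair of libraries was compared by a chi-square statistic of the counts of the more abundant genes. Over 60 pairs the chi-square per degree of freedom ranged from 5.17 to 53.4, so no pair agreed within sampling noise. Libraries made separately from 1 rat could also exceed that noise, so this does not show that the rats differ. Each library counts as 1 replicate because each is described as 1 rat. The labels name no sequencing batch that differs between libraries.

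The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr on the groups, robust quasi-likelihood fit). One model with the 6 groups and no covariate gave all comparisons, so that the groups share an estimate of the spread. The filter kept 14801 genes, which hold 99.941% of all counts. The common dispersion was 0.0144, a biological coefficient of variation of 12%. Adjusted p values are Benjamini-Hochberg values over the genes of a comparison, with a threshold of 0.05. Standard errors were derived from the fold change and its F statistic, and 95% intervals from them. Injured rats of 1 and 12 weeks were compared with sham rats of the same week, and those of 3 and 6 weeks with the mean of both sham groups. Further contrasts were sham 12 weeks against sham 1 week, the difference between the injury effects at 12 and 1 weeks, a joint test among the 4 injured groups and all injured against both sham groups. Levels per rat are counts scaled to a common library total (CPM) after TMM scaling, and a library total of 6459555 counts is written as 6.46 M counts. The test was checked on simulated counts drawn from the means, dispersions and library sizes of the real genes, and the other statistics on simulated values.

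Principal components, shares of variance, scores and correlations used log2 CPM with a prior count of 2, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Comparisons of 5 rats with 5 used exact two-sided permutation tests over 252 splits, whose smallest p is 0.00794. The share of variance over 6 groups used 100000 permutations. Total counts and the share of the 10 most abundant genes were compared between groups in the same way, with 10 tests adjusted together.

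The genes named were to be those with a gene symbol and the smallest p in each direction past the threshold, 6 per direction, and members of gene lists fixed beforehand. Pseudogenes and symbols that are only a locus number were to be passed over. The reference table used here, on assembly GRCr8, has 47357 rows and none with an identifier of the kind in the files, so 0 of the 32545 identifiers could be given a symbol. The rule was therefore reduced to the 2 identifiers per direction with the smallest p past the threshold, and no coordinates are given. For the same reason the 38 gene lists, the cell type scores, the share of mitochondrial genes and the covariate for white matter content were not run.

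Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, a filter at 1 CPM in 5 libraries, a fit without robust estimation, DESeq2 1.42.0, limma-voom (limma 3.58.1), a threshold of 0.1, the replicate number as a block, 2 surrogate variables (sva 3.50.0), other reference groups, only the compared groups in the fit, and each library left out in turn. Library size as a covariate, leaving out the 4 libraries under 9 M counts, leaving out 2 libraries far from the others on the principal components, and the alternatives for the scores, shares, correlations and library composition were chosen after seeing the data.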

Results

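The series asked how gene expression in a region of the cervical spinal cord changes after an injury lower down, at thoracic level. The region sampled was the intermediate gray matter (laminae IV to VII, both sides) at the third cervical vertebral level. The series title describes it as the target region of sprouting hindlimb corticospinal fibres, the axons that run from the motor cortex to the spinal cord and that lose their lumbar targets when the thoracic cord is damaged. The tissue therefore lay above the lesion and was not itself cut. Adult female Long Evans rats received a thoracic spinal cord injury (SCI) or a sham operation. Total RNA was depleted of ribosomal RNA and sequenced as strand-specific libraries, 1 library per rat.

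The 30 libraries fell into 6 groups of 5 rats. Sham rats were taken at 1 week and at 12 weeks after surgery, and injured rats at 1, 3, 6 and 12 weeks. Each library listed counts for 32545 gene identifiers. Library totals ranged from 6459555 (6.46 M) to 37410793 (37.4 M) counts. Gene levels are given as CPM, counts scaled to a common library total. The mean totals were 21.7 M ± 9.89 (SD, n = 5) for sham 1 week, 14.5 M ± 2.64 for sham 12 weeks, 15.8 M ± 2.27 for SCI 1 week, 13.1 M ± 3.33 for SCI 3 weeks, 9.67 M ± 2.73 for SCI 6 weeks and 18.1 M ± 10.1 for SCI 12 weeks. The files do not pair their gene identifiers with gene names, so genes are given by identifier and what they encode is not stated. Gene groups and cell types were for the same reason not tested.

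The labels of 1 library conflict. Sham 1 week replicate 1 is a control by its title and its description, whereas its surgery and source fields name a spinal cord injury. It was kept as sham, because the design text gives 5 rats per group and 5 other libraries are titled as injured at 1 week. The count of changed genes at 1 week rests on this choice, as given with that comparison.

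The groups accounted for a small part of the variation between rats. Of the summed squared distances between the 30 libraries, 19.4% lay between the 6 groups, against 17.2% for random grouping (permutation test with 100000 permutations, p = 0.00368, Benjamini-Hochberg adjusted p = 0.0147 over 4 such tests). Between SCI 1 week and sham 1 week the share was 15.2%, against 11.1% for random grouping (exact permutation test over 252 splits, p = 0.0159, adjusted p = 0.0318). It was 11.7% between SCI 12 weeks and sham 12 weeks (exact permutation p = 0.27) and 12.9% between the sham groups of 12 weeks and 1 week (exact permutation p = 0.111). The first principal component held 8.37% of the variance and the second 7.35%. These shares, the scores and the correlations given further on were computed after the counts of changed genes had been seen.

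**Figure D1:**
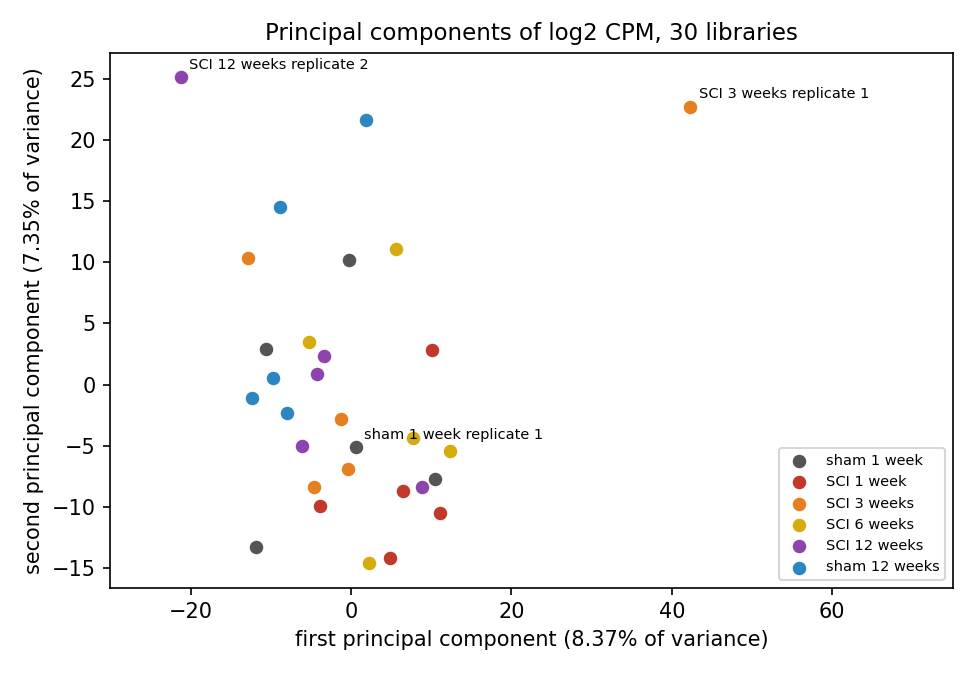
Each point is 1 library, placed by the first (horizontal) and second (vertical) principal component of log2 CPM over 14801 genes, coloured by group. The groups overlap, and SCI 3 weeks replicate 1 lies at 42.3 on the first component.

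The first comparison asked what differed in this region 1 week after injury, with sham rats of the same week as the reference. Of 14801 genes tested, 53 differed, of which 25 were higher and 28 lower after injury (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The changes were small. The absolute log2 fold change of these genes had a median of 0.40 and a range of 0.26 to 1.85, 11 of them reached 1.5-fold and 3 reached 2-fold. In 40 of the 53 genes, which were chosen on these same rats, every injured rat lay on the same side of every sham rat. Over all tested genes this held for 519, or 3.51%, where chance gives 0.794% for 5 against 5 on average over splits. Genes are not independent of each other, so a single split can lie far from that average. The share was not computed for other splits, and the excess was not tested.

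The 4 genes named here had the smallest p in each direction. ENSRNOG00000036866 rose from 60.9 ± 2.97 CPM (SD, n = 5) in sham 1 week to 75.1 ± 2.37 in SCI 1 week, a log2 fold change of 0.30 with a standard error of 0.058 (edgeR, adjusted p = 0.0238). ENSRNOG00000008788 rose from 138 ± 6.55 to 165 ± 4.98 CPM, a log2 fold change of 0.26 with a standard error of 0.053 (edgeR, adjusted p = 0.0238). ENSRNOG00000002635 decreased from 61.1 ± 3.74 to 46.8 ± 2.36 CPM, a log2 fold change of -0.39 with a standard error of 0.067 (edgeR, adjusted p = 0.0112). ENSRNOG00000039876 decreased from 25.2 ± 3.38 to 15.5 ± 2.09 CPM, a log2 fold change of -0.71 with a standard error of 0.123 (edgeR, adjusted p = 0.0112). In all 4 genes the ranges of the 5 injured and the 5 sham rats did not overlap. The genes were chosen by their small p between these same rats, which favours such a separation, so it is not separate support.

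**Figure D2:**
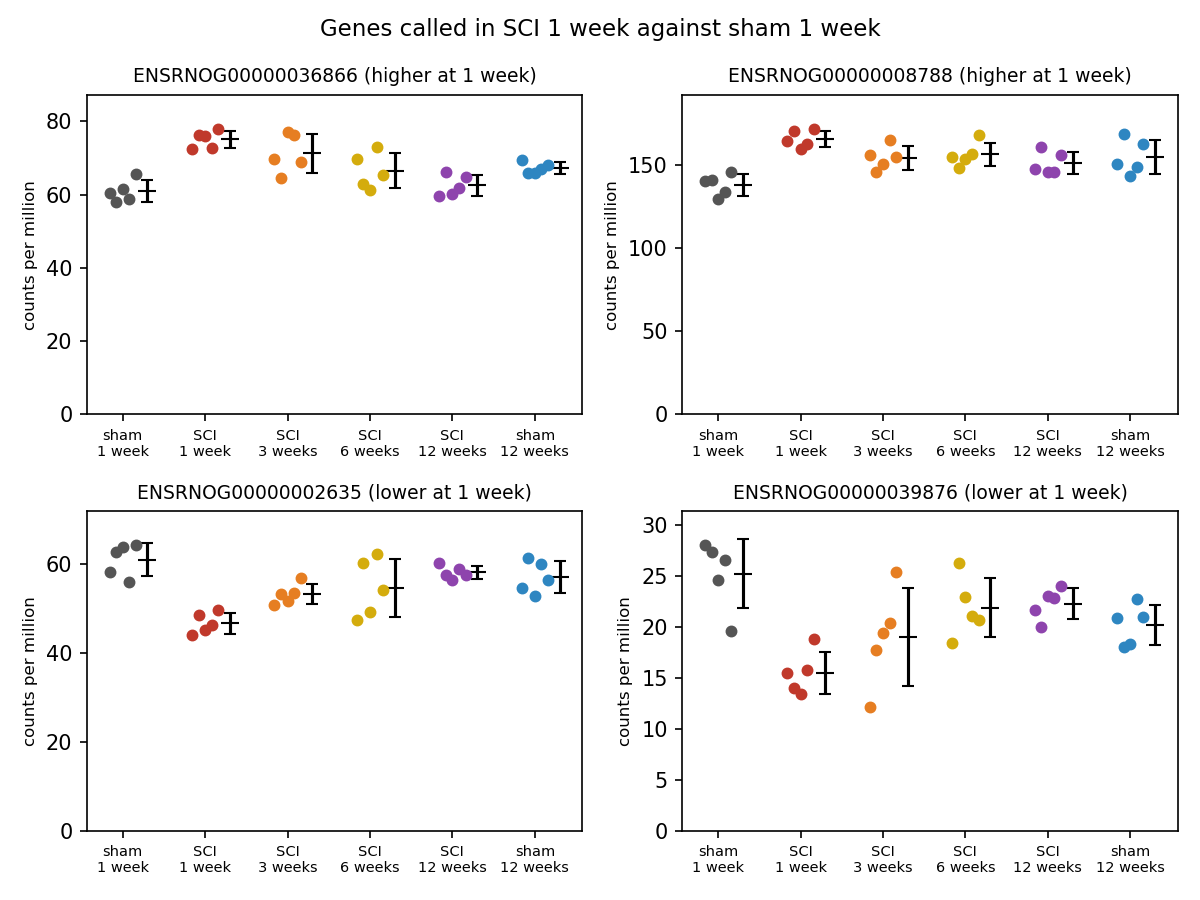
CPM (vertical, from 0) of the 4 genes in each of the 30 rats, by group, with 1 point per rat and the group mean and SD as a bar beside them. At 1 week the injured rats lie above the sham rats for ENSRNOG00000036866 and ENSRNOG00000008788 and below them for ENSRNOG00000002635 and ENSRNOG00000039876. The genes were chosen on the groups of 1 week, which favours this separation.

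The count of 53 was fragile. It fell to 1 without the library with conflicting labels and to 0 with that library counted as injured. Without it ENSRNOG00000002635 still passed (edgeR, adjusted p = 0.0266), and the other 3 named genes kept log2 fold changes of 0.30, 0.27 and -0.66 at an adjusted p of 0.0525 each. With it counted as injured none of the 4 passed (edgeR, adjusted p from 0.167 to 0.268, the highest over the alternatives). The count was also 1, 0 and 3 without SCI 1 week replicates 2, 3 and 4, and 3 and 2 without sham 1 week replicates 3 and 4, and it was 128 without SCI 3 weeks replicate 1, a library of neither compared group, with 14929 genes tested. With log2 library size as a covariate 2 genes passed, and the median log2 fold change of the 53 genes, signed by direction, went from 0.403 to 0.397 with adjusted p of at most 0.105, while DESeq2 called 219 and limma-voom 164 in the same comparison.

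**Figure D3:**
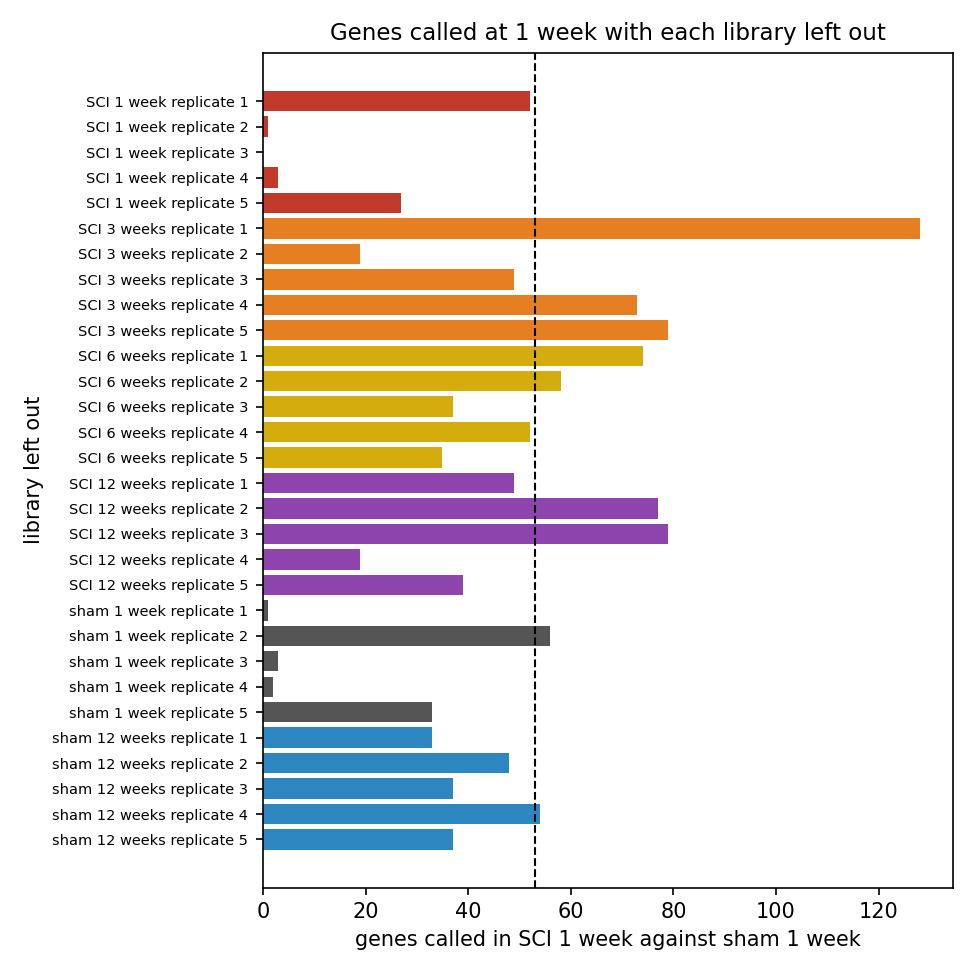
Number of genes called in SCI 1 week against sham 1 week (horizontal, from 0) with each of the 30 libraries left out in turn (vertical), coloured by the group of that library, with the 53 genes of the full set as a dashed line. Leaving out single libraries of the compared groups brought the count down to between 0 and 3 in 6 cases, and leaving out SCI 3 weeks replicate 1 raised it to 128.

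At 3 weeks the reference was the mean of both sham groups, since sham rats were taken at 1 and 12 weeks. No gene passed the adjusted threshold in SCI 3 weeks (edgeR quasi-likelihood test, smallest adjusted p = 0.462). The unadjusted p was under 0.05 for 1052 genes, 7.11% of those tested, and DESeq2 called 1 gene and limma-voom 0. The 95% confidence interval of the fold change excluded a 2-fold difference in either direction for 92.3% of genes and a 1.5-fold difference for 79.4%.

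At 6 weeks, against the same reference, no gene passed either (edgeR, smallest adjusted p = 0.11). The unadjusted p was under 0.05 for 1216 genes, 8.22% of those tested, DESeq2 called 1 gene and limma-voom 0, and the interval excluded a 2-fold difference for 91.1% of genes. The SCI 6 weeks libraries were the shallowest, with a mean that differed from that of the 10 sham libraries by -8.44 M counts (exact permutation test, p = 0.0263, adjusted p = 0.132 over 10 tests of library composition).

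At 12 weeks, against sham rats of the same week, no gene passed (edgeR, smallest adjusted p = 0.856). The unadjusted p was under 0.05 for 785 genes, 5.3% of those tested, and DESeq2 and limma-voom each called 0. The interval excluded a 2-fold difference for 90% of genes and a 1.5-fold difference for 76.3%. The 10 most abundant genes held a lower share of the counts in SCI 12 weeks, 10.3% ± 1.09 (SD, n = 5), than in sham 12 weeks, 11.8% ± 0.278 (exact permutation p = 0.00794, the smallest that 5 against 5 can give, adjusted p = 0.0794).

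Because no gene passed at 12 weeks, the planned overlap of the genes changed at 1 and at 12 weeks was empty. Whether the effect of injury differed between 1 and 12 weeks was tested directly as an interaction. No gene passed (edgeR, smallest adjusted p = 0.0548), the unadjusted p was under 0.05 for 1240 genes, and DESeq2 called 18 genes and limma-voom 3. The 53 genes of 1 week were therefore not shown to respond differently at 12 weeks in the edgeR test. That test was adjusted over all genes, not over the 53. The 2 genes per direction with the smallest interaction p included ENSRNOG00000039876, ENSRNOG00000036866 and ENSRNOG00000002635, named at 1 week, but not ENSRNOG00000008788. Their interaction log2 fold changes of 0.858, -0.407 and 0.412 had the opposite sign to those at 1 week (edgeR, adjusted p = 0.0906, 0.0906 and 0.2). Choosing genes on the rats of 1 week favours that sign, so no loss of the change is read from it.

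The 53 genes were followed over time as a score, the mean over genes of log2 CPM, each gene signed by its direction at 1 week, relative to sham 12 weeks. The score was 0.334 ± 0.058 (SD, n = 5) in SCI 1 week and -0.164 ± 0.091 in sham 1 week, a gap that the choice of the genes produces and that was not tested. The same choice favours a drop from SCI 1 week to any later group, so that drop is not read as a decay over time. It was 0.131 ± 0.13 in SCI 3 weeks, 0.055 ± 0.104 in SCI 6 weeks and -0.014 ± 0.023 in SCI 12 weeks, against 0 ± 0.064 in sham 12 weeks. None of these differences passed an exact two-sided permutation test (p = 0.103, 0.365 and 0.69, adjusted p = 0.309, 0.547 and 0.69). In SCI 3 weeks 47 of the 53 genes lay on the side they had at 1 week, in SCI 6 weeks 36 and in SCI 12 weeks 21. These counts were not tested, since the genes are not independent of each other. Of the 18 genes called with only the 2 groups of 1 week in the fit, 14, 11 and 6 did so, and their score did not pass either (exact permutation p = 0.333, 0.603 and 0.849). Without SCI 3 weeks replicate 5 the difference at 3 weeks was 0.173 (exact permutation p = 0.0238), and without SCI 3 weeks replicate 1, the rat with the highest score of its group, it was 0.09 (exact permutation p = 0.206). The difference at 6 weeks was 0.013 without SCI 6 weeks replicate 1 (exact permutation p = 0.77).

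**Figure D4:**
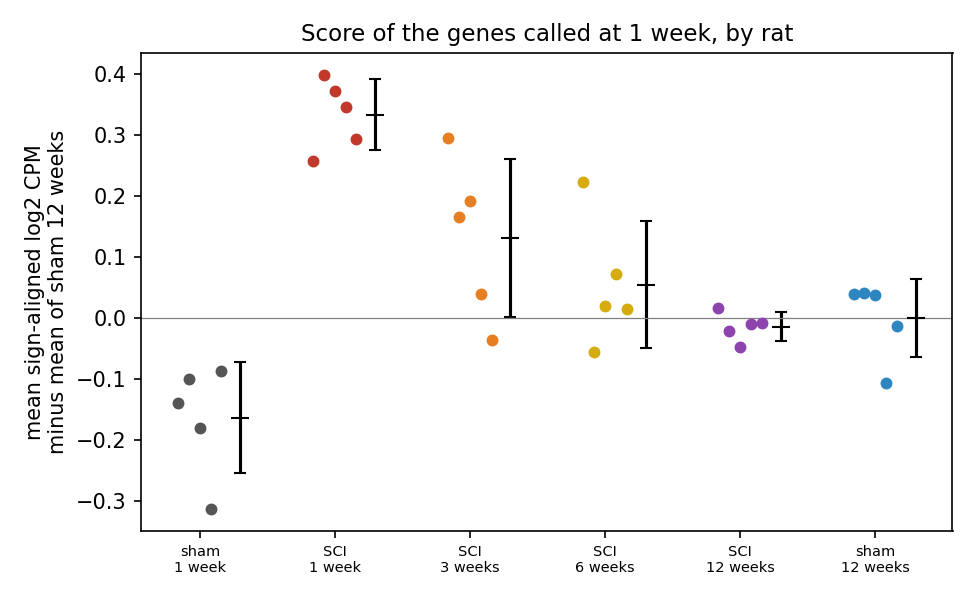
Score of the 53 genes (vertical, mean signed log2 CPM minus the mean of sham 12 weeks) in each of the 30 rats by group, with 1 point per rat and the group mean and SD as a bar. The means are 0.334 in SCI 1 week, 0.131 in SCI 3 weeks, 0.055 in SCI 6 weeks and -0.014 in SCI 12 weeks. The genes and their signs were chosen on the groups of 1 week, which favours a drop from SCI 1 week to the later groups.

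The changes at 1 week were also compared across all 14801 genes with those at later times, using sham 1 week for the first and sham 12 weeks for the second so that no library entered both. Across genes, which are not independent replicates, the log2 fold changes at 1 week correlated with those at 3 weeks with a Pearson r of 0.175 and a Spearman rho of 0.243 (exact permutation of the rats, p of r = 0.0402). The r was 0.146 at 6 weeks, with a rho of 0.188 (exact permutation p = 0.0493), and 0.112 at 12 weeks, with a rho of 0.081 (exact permutation p = 0.161). After adjustment over the 3 correlations none passed (adjusted p = 0.0739, 0.0739 and 0.161). The 3 correlations share the changes at 1 week and the sham 12 weeks rats, so they are not separate from each other. Without sham 12 weeks replicate 4 the r fell to 0.099, 0.073 and 0.03. Without sham 1 week replicate 2 it rose to 0.217, 0.201 and 0.145.

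The time course asked which genes differed among the 4 injured groups. In the joint test 5 genes passed (edgeR quasi-likelihood F-test). ENSRNOG00000001859 was lowest at 1 week, with 7.95 ± 1.36 CPM (SD, n = 5), and stood at 9.73 ± 1.52 at 3 weeks, 13.4 ± 1.85 at 6 weeks and 14 ± 1.66 at 12 weeks (edgeR, adjusted p = 0.024). Its level was 13.1 ± 3.35 in sham 1 week and 15.6 ± 1.96 in sham 12 weeks. ENSRNOG00000023338 decreased from 292 ± 28.3 CPM at 1 week to 212 ± 25.8 at 12 weeks (edgeR, adjusted p = 0.024), with 265 ± 13.6 in sham 1 week and 252 ± 16 in sham 12 weeks. ENSRNOG00000015445 decreased from 476 ± 65 at 1 week to 363 ± 32.1 at 6 weeks and 371 ± 33.5 at 12 weeks (edgeR, adjusted p = 0.0284), and its sham levels were 493 ± 51.4 at 1 week and 408 ± 25.3 at 12 weeks. The other 2 genes were lower at 12 weeks than at 1 week. The count of 5 was 0 without any 1 of SCI 1 week replicates 1, 3 and 4, SCI 6 weeks replicate 2 or SCI 12 weeks replicate 3, it was 0 with sham 1 week replicate 1 counted as injured, and DESeq2 called 29 genes. Of 100 splits of the 20 injured rats, the real one included, 5 gave at least as many genes.

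Time after the operation without injury was read from the sham groups. No gene differed between sham 12 weeks and sham 1 week (edgeR, smallest adjusted p = 0.199). The unadjusted p was under 0.05 for 1219 genes, DESeq2 called 2 genes and limma-voom 0, and the interval excluded a 2-fold difference for 90.3% of genes. The mean of all 4 injured groups against the mean of both sham groups, the comparison with the most rats, gave no gene either (edgeR, smallest adjusted p = 0.151). There the unadjusted p was under 0.05 for 1931 genes, 13% of those tested, DESeq2 called 16 genes and limma-voom 0, and the interval excluded a 2-fold difference for 97.3% of genes and a 1.5-fold difference for 88.2%.

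The size of change that these libraries could show was estimated on simulated counts with 50 genes changed at each fold. Each comparison was simulated once, with its own random genes and each gene drawn on its own, so the rates are approximate. Differences in rate between comparisons were not tested. The changes of all folds were present together, and a larger number of changed genes makes the adjusted threshold easier to pass. In SCI 1 week against sham 1 week, the test recovered 16% of genes changed by 0.32 on the log2 scale, 60% at 1.5-fold, 80% at 2-fold and 86% at 3-fold, over 14801 genes, and 5 of its 126 calls were of unchanged genes. In SCI 12 weeks against sham 12 weeks it recovered 42%, 52%, 78% and 90% at the same sizes, and in all injured against both sham groups 62%, 84%, 92% and 100%. Calls of unchanged genes were 6 of 137 in the former and 12 of 181 in the latter. In SCI 3 weeks against both sham groups they were 13 of 164.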

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

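The explanations below and their tests were written down before the tests were run but after the counts of changed genes and the principal components had been seen. The number of splits drawn was set after the real counts were known. Other settings chosen after the results were seen are the repeated thinning, the minimum of 20 counts and the 50 genes per position.

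A library far from its group was sought in 72 sets of 5 rats (totals, share of the 10 most abundant genes, first 2 principal components, score, 7 named genes). It was found in 1, where chance at 1 in 20 gives 3.6, so the number found is no more than chance gives. SCI 3 weeks replicate 1 stood at 42.3 on the first principal component, with the other 4 rats of its group between -12.9 and -0.4. At 8.1 M counts it is the shallowest of its group, and low depth was tested by thinning all libraries to 6.46 M counts. Its gap to the nearest rat over the range of the group was 0.774 before thinning and 0.662 in the first draw after it, and over 20 draws the ratio ran from 0.637 to 0.719, with 3 draws still past the critical ratio. The first draw met the bound set beforehand for depth as the cause, as did all but those 3 of the 20 draws, and the draws after the first were added once it had been seen. The draws thin the same libraries again, so they are not separate tests of depth. Depth cannot be told apart from other causes, because 3 draws lay past the bound and shallower libraries did not stand as far out. SCI 6 weeks replicates 1 and 2, with 6.46 and 7.04 M counts, lay at 12.3 and 2.2 on the same component. SCI 12 weeks replicate 2, with 8.13 M counts, goes the other way. It lay at -21.2 on that component, the lowest of the 30 libraries, and at 25.1 on the second, the highest. Tissue from outside the region was sought as genes that other libraries lack. This library held 40 genes at 4 times or more the highest value of the other 29 libraries, against up to 127 in another library, and 27 of the 30 libraries, this one included, held 0 such genes with at least 20 counts. The bound set beforehand was wrong, because neighbouring cord tissue shares its genes with the region and need not bring such genes, so that this explanation cannot be told apart either. No biological explanation was tested for a single rat.

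For the 53 genes that differed between SCI and sham at 1 week, chance was tested with other splits of the same 10 rats. Of 100 splits, 2 gave as many genes, the real one included, and 95 gave 0. That is under the share set beforehand for chance, which argues against chance for this comparison taken alone. Chance is not excluded, because the share is not adjusted for the other comparisons and another split gave more genes. The other split gave 123 genes and exchanged SCI 1 week replicate 1 with sham 1 week replicate 2, with the other 8 rats under their own labels. The next highest count was 5, and why that exchange gave more genes was not tested. Library depth as the whole source is argued against by the fold changes. With log2 library size as a covariate their median went from 0.403 to 0.397, a ratio of 0.986. All 53 kept their direction, while the median standard error went from 0.0923 to 0.0963. The calls ended for 51 genes because their adjusted p moved past the threshold, to at most 0.105.

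A programme that varies between rats whatever their group stays open for the same genes. In the 20 rats outside the comparison, with group means removed, the signed genes correlated with each other with a mean of 0.286, above the 95th percentile of 0.069 and the median of 0.032 of 1000 random sets matched on expression. These genes may therefore move together in rats that differ in something other than the injury at 1 week, such as the dissection or the state of the animal, and an effect of injury on the same programme, the biological explanation the design gives, is not excluded. Whether sham 1 week replicate 1 is mislabelled cannot be told apart, although the values go the way of its title. Held out, it lay at 0.36 between the sham mean at 0 and the SCI mean at 1, the lowest of the 10 rats, and ENSRNOG00000002635, called without this library, stood in it at 58.3 CPM, within the sham range of 56 to 64.3 and above the SCI range of 44 to 49.7. The other 3 genes named at 1 week, ENSRNOG00000036866 at 60.5, ENSRNOG00000008788 at 140 and ENSRNOG00000039876 at 28 CPM, also stood on the sham side of the SCI ranges, but they were chosen with this library counted as sham. The question stays open because the other held-out sham rats at 0.4 to 0.62 overlap the held-out SCI rats at 0.46 to 0.74, and the levels of single genes, looked up after the result was seen, decide nothing.

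The 5 genes of the time course can be had by chance, since 5 of 100 splits of the 20 injured rats gave at least as many genes, with up to 20 in another split. The comparisons with 0 genes cannot exceed any split. All 40 of 40 splits gave as many, and the highest other count was 4 for SCI 3 weeks, 30 for SCI 6 weeks, 1 for SCI 12 weeks, 5 for sham 12 weeks against sham 1 week, 0 for the interaction and 3 for all injured against both sham groups.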

How the results depend on the processing

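Library size as a covariate, leaving out shallow or outlying libraries, and all alternatives for scores, correlations, shares and library composition were chosen after seeing the data. Where a cause is not named, the cause was not tested.

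The count of 53 genes at 1 week was 169 at a threshold of 0.1, 164 with limma-voom, 219 with DESeq2 and 109 with 2 surrogate variables. It was 2 with log2 library size as a covariate and 0 with sham 1 week replicate 1 counted as SCI. With only the compared groups in the fit, where 14425 genes were tested, it was 18, of which 15 were among the 53. With both sham groups as reference it was 171, of which 42 were among the 53. It was 176 without the 4 libraries under 9 M counts and 157 without the 2 libraries far out on the components. With single libraries left out it ran from 0 to 128. It was 1, 0, 3 and 27 without SCI 1 week replicates 2, 3, 4 and 5, and 1, 3, 2 and 33 without sham 1 week replicates 1, 3, 4 and 5. It was 128 and 19 without SCI 3 weeks replicates 1 and 2, 19 without SCI 12 weeks replicate 4, 35 without SCI 6 weeks replicate 5 and 33 without sham 12 weeks replicate 1.

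The count of 5 genes in the time course was 8 at a threshold of 0.1, 29 with DESeq2, 26 with 2 surrogate variables, 0 with sham 1 week replicate 1 counted as SCI, 0 without the libraries under 9 M counts and 9 without the 2 libraries far out, and ran from 0 to 9 with single libraries left out. It was 0 without SCI 1 week replicate 1, 3 or 4, SCI 6 weeks replicate 2 or SCI 12 weeks replicate 3, 2 without SCI 3 weeks replicate 2, SCI 6 weeks replicate 3 or sham 1 week replicate 4, 3 without SCI 3 weeks replicate 3, 4 or 5 or SCI 12 weeks replicate 4, and 9 without SCI 12 weeks replicate 2. The interaction gave 3 genes at a threshold of 0.1, 1 without robust estimation, 3 with limma-voom, 18 with DESeq2, 5 with 2 surrogate variables, 2 without the libraries under 9 M counts and 2 without the 2 far out, and 0 to 2 with single libraries left out. DESeq2 gave 1 gene in SCI 3 weeks, 1 in SCI 6 weeks, 2 between the sham groups and 16 in all injured against both sham groups. With 2 surrogate variables the last 2 gave 1 and 3 genes, and with only the compared groups in the fit the sham groups differed in 4. Single libraries left out gave 0 to 1 genes in SCI 6 weeks, SCI 12 weeks and all injured against sham, and 0 to 2 between the sham groups.

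No pairing of the rats by replicate number was seen on average. Same-numbered rats of different groups had a mean correlation of 0.001, against 0 for different-numbered rats. The same-numbered pairs ran from -0.385 to 0.311, with 19 of 75 over 0.1. That share was not computed for different-numbered pairs, so a pairing within some groups is not excluded. With the replicate block 54 genes differed at 1 week, 3 in the time course and 1 between the sham groups.

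The 7 named genes kept their direction in all 302 refits and lost their call in 54. They were chosen by their small p in these same libraries, and most refits share nearly all libraries, so the kept direction is not separate support. The 4 genes of 1 week lost it in 9, 9, 2 and 4 of 44 refits, in the order named, with adjusted p up to 0.268, and the 3 of the time course in 7, 7 and 16 of 42, with adjusted p up to 0.486. At a prior count of 0.5 the correlation of the changes at 1 week with those at 3 weeks was 0.144 and with those at 6 weeks 0.112. With single libraries left out they ran from 0.099 to 0.217 and from 0.073 to 0.201, and the correlation with 12 weeks from 0.03 to 0.145. The difference in score ran from 0.09 to 0.173 at 3 weeks, from 0.013 to 0.082 at 6 weeks and from -0.041 to -0.004 at 12 weeks. The share between the sham groups ran from 13.7% to 15.1%, where random grouping of 9 rats gives 12.5% against 11.1% for 10 rats, with an exact permutation p of 0.0317 at 14.9% without sham 1 week replicate 3. The difference in M counts ran from -8.74 to -2.04 for SCI 1 week, from -5.89 to -2.91 for SCI 3 weeks, from -9.28 to -6.3 for SCI 6 weeks, from -0.252 without SCI 12 weeks replicate 3 to 6.09 for SCI 12 weeks (3.6 with all libraries, exact permutation p = 0.508) and from -10 to -3.32 between the sham groups, and the share of the 10 most abundant genes between the sham groups from 0.775 to 1.34 points. The planned gene lists, their camera and fry tests and the white matter covariate were not run, because no identifier could be given a symbol.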

Other observations

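The held-out positions of the 10 rats of 1 week, computed after the count of 53 had been seen, ran from 0.46 to 0.74 for the injured and from 0.36 to 0.62 for the sham rats. Each used the 50 genes that best separated the remaining 9 rats. The direction found in 9 rats thus placed the rat left out with wide overlap between the groups. SCI 1 week replicates 1, 3 and 4, at 0.47, 0.5 and 0.46, lay below sham 1 week replicates 2 and 5, at 0.55 and 0.62.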
